A study of Mus musculus with 2 samples.

How the data were processed

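Acetylation of histone H3 at lysine 9 (H3K9ac) was profiled by ChIP-seq, the sequencing of DNA bound to an immunoprecipitated protein, in kidney tissue of mouse embryos at day 16.5. The labels define 1 group with 2 biological replicates, each made from pooled embryos of both sexes of strain B6NCrl. The label of replicate 2 gives 41 embryos; that of replicate 1 gives no number. The fragment size range was 300 to 500 bp per the labels.

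Peaks had been called on filtered alignments to mm10 with a control, per the file headers of the deposited descriptions. There were 4 deposited peak lists, from replicate 1, from replicate 2, from both together (the pooled list) and a replicated list derived from the other 3. The aligner, the peak caller, its threshold and the rule for keeping a replicated peak are not given in the sources used here. The deposited signal value of each peak is the authors' own measure of enrichment, and its exact definition is not given either. It was used to describe, rank and filter peaks within a list, was summed by width in 1 alternative, and was set side by side between lists only in the correlation of the replicates and for Nek8. The deposited −log10 p and −log10 q of each peak were made by the authors' peak caller, and the −log10 q was used only as a filter in alternatives. The deposited summit position was used to centre windows for the motif search. Read counts were not used here, so the depth of each replicate is unknown. The 2 text files of descriptions held no measurements and were left out.

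All positions are in mm10, counted from 1. The peaks of each list were used as deposited, without merging, and chromosomes 1 to 19, X and Y were used. The reference was the GRCm38 sequence with the GENCODE M21 annotation, and 21938 protein-coding genes were analysed. A promoter was the sequence within 1000 bp of the transcription start site (TSS) of any annotated transcript, and a gene was called marked when a peak overlapped its promoter by at least 1 bp. The promoter signal of a gene was the highest signal value among its promoter peaks, and ranks run from 0 for the weakest to 100 for the strongest of the marked genes. The CpG content of a promoter was the observed/expected ratio within 500 bp of the gene's 5′ end. A merged domain joined replicated peaks across gaps up to 1000 bp. A distal peak lay more than 1000 bp from any TSS. Distances from a named peak to the nearest coding TSS run from its summit.

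The 26 gene lists, the 18 consensus words, the tests, 47 alternatives and the rule for naming genes were fixed before the data were examined. The lists hold textbook markers of kidney cell types, of other tissues, of disease and signalling groups, and of the olfactory receptor and ribosomal protein families. The symbol Ahsp was not found in the annotation and was left out. Each list's share of marked genes was compared with that of all other genes by a two-sided Fisher's exact test, and with 10000 random lists matched on decile of promoter CpG content. Median ranks of signal and of domain width were compared with 10000 random lists of marked genes, a resampling test. Distal peaks within 50000 bp of a gene's TSS were compared with 10000 random lists matched on promoter state and decile of gene span, also a resampling test. All random lists were drawn with replacement from genes that included the list's own members. Consensus words were counted in the 500 bp around distal summits and in flanks 3000 bp away outside any peak, by Fisher's exact test, beside the same word reversed. Each family of p-values was adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Genes and windows are not replicates, so these p-values describe these peak lists and not a population of embryos. The smallest p that the random lists can give is 0.0002. Intervals of shares are exact (Clopper-Pearson) at 95% and cover counting error only.

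Named genes were the 4 marked members of highest signal in the 8 lists with the largest and the 8 with the smallest share, and up to 4 unmarked members of each list in list order. The rule also named the 10 genes with the widest domain, the 10 strongest distal peaks, all Hox genes and, per replicate, the 5 strongest peaks without an overlap in the other. The same members of other lists were named after their values were seen.

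The replicates were compared by the share of peaks that overlapped, beside 100 random placements on the same chromosomes. With 1 group of 2 replicates, no test between groups was possible. Alternatives changed the promoter window, the peak threshold, the minimum overlap, the peak list, the TSS definition, the background, the strength measure, the distances, the motif window and flanks and the joining gap, and left out each replicate. A further 3 alternatives were chosen after seeing the data.

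The steps were tested on simulated data for the same 21938 genes with lists of 25. Fisher's exact test recovered 80 of 80 planted lists and called 2 of 200 unchanged lists. The planted lists were unmarked, marked at a low share or marked in full, so intermediate shares were not tried. On 40 CpG-rich lists with no effect of their own, Fisher's exact test called 40, and the CpG-matched random lists called 0. In these lists nearly all genes were marked, so the matched test could hardly have called them higher. No planted effect was given to the matched test, so its power is unknown. The matched lists for distal peaks recovered 39 of 40 lists with doubled counts and called 1 of 40 unchanged lists. This recovery does not give the power of the adjusted test on the real lists. There, podocyte genes, with 5.09 peaks per gene against 2.55 in matched lists, did not pass, nor did retinoid signalling genes, with 4.74 against 2.27. The overlap step found all 39970 copied peaks, and the motif step found the planted AP-1 word and called 0 of 17 others. The copied peaks were exact copies, so their full recovery was fixed in advance and checks the counting only. Simulated windows and flanks had the same base composition. The motif check thus does not cover false calls from differences in composition. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0 and matplotlib 3.10.9.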

Results

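H3K9ac, a histone mark found at active promoters and enhancers, was mapped in embryonic mouse kidney at day 16.5, a stage when nephrons are still forming. There was 1 group with 2 biological replicates of pooled tissue. The replicates' own lists held 79911 and 71334 peaks, the pooled list 76221 and the replicated list 44406. The replicated list covered 37.5 Mb, with a median peak width of 555 bp. It was used throughout unless a replicate is named. All 44406 replicated peaks were also in the pooled list. Of them, 38641 (87.0%) shared at least 50% of either peak with both replicates, 5605 with 1 replicate only and 160 with neither. Read depth is unknown, so a missing peak is not an absence of the mark. Signal values of single genes come from 1 list and have no error of their own.

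The first comparison asked where in the genome the mark lay. Promoters of protein-coding genes held 59.4% of the marked bases but 3.70% of the genome, a 16.0-fold excess. Introns and intergenic sequence were underrepresented, at 0.613-fold and 0.267-fold. Promoters held 48.9% of the replicated peaks and, in the replicates' own lists, 36.0% ± 1.79 (SD, n = 2). In bases, the replicates had 54.1% ± 0.943 (SD, n = 2) at promoters. A promoter peak stood at 14414 of 21938 protein-coding genes (65.7%, exact interval 65.1 to 66.3), against 67.4% ± 0.432 (SD, n = 2) in the replicates' own lists. Both replicates marked 14397 genes, 94.9% of the 15167 marked in either. Marking rose with the CpG content of the promoter: 6.24% of genes were marked in the lowest decile, 78.1% in the fifth and 98.5% in the highest. No test was made of these shares.

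The second comparison asked which cell types' genes carried the mark. All 20 nephron progenitor genes and all 18 renal vesicle genes had a promoter peak, in the replicated list and in each replicate. Among the progenitor genes, the highest signal values were at Sall1, a zinc-finger factor needed for kidney outgrowth (30.7, chromosome 8, 89039420 to 89046534), and Pax2, a paired-box regulator of nephron formation (21.9, chromosome 19, 44754921 to 44758474). Hoxa11, a homeobox gene of the metanephric mesenchyme, had 20.3, and Wt1, a factor of progenitors and podocytes, had 19.3 over a peak of 11128 bp. In the renal vesicle list they were Pax8, which specifies nephron fate (22.98), the Notch ligand Jag1 (22.7), Sox9 (14.6) and the Iroquois gene Irx3 (14.6). Of 25 ureteric bud and collecting duct genes, 24 were marked (96.0%, exact interval 79.6 to 99.9). Hoxb7 (33.4, a peak shared with Hoxb8), the FGF and RET antagonist Spry1 (30.4), Emx2 (20.9) and the epithelial factor Grhl2 (18.8) were the strongest, and the vasopressin receptor gene Avpr2 had no peak. Of 22 podocyte genes, 21 were marked (95.5%), led by the slit diaphragm adaptor Cd2ap (33.3), Dach1 (31.1), Foxc1 (30.1) and Actn4 (29.6). The nephrin gene Nphs1 had a promoter peak in replicate 1 but not in replicate 2 or the replicated list.

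Each of these 4 shares was higher than that of other genes by Fisher's exact test, with adjusted p of 0.00112, 0.00145, 0.00112 and 0.00421 in the same order. Against lists matched on promoter CpG content, none of the 4 calls held: the matched means were 90.3% ± 6.13, 91.7% ± 5.33, 79.3% ± 6.44 and 86.4% ± 5.69 (SD over random lists), with adjusted p of 0.29955, 0.314, 0.0555 and 0.29955. The nephron progenitor and renal vesicle lists were already marked in full, and many matched lists were too. The matched test thus could not have called these lists higher, and its outcome for them decides nothing.

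**Figure D1:**
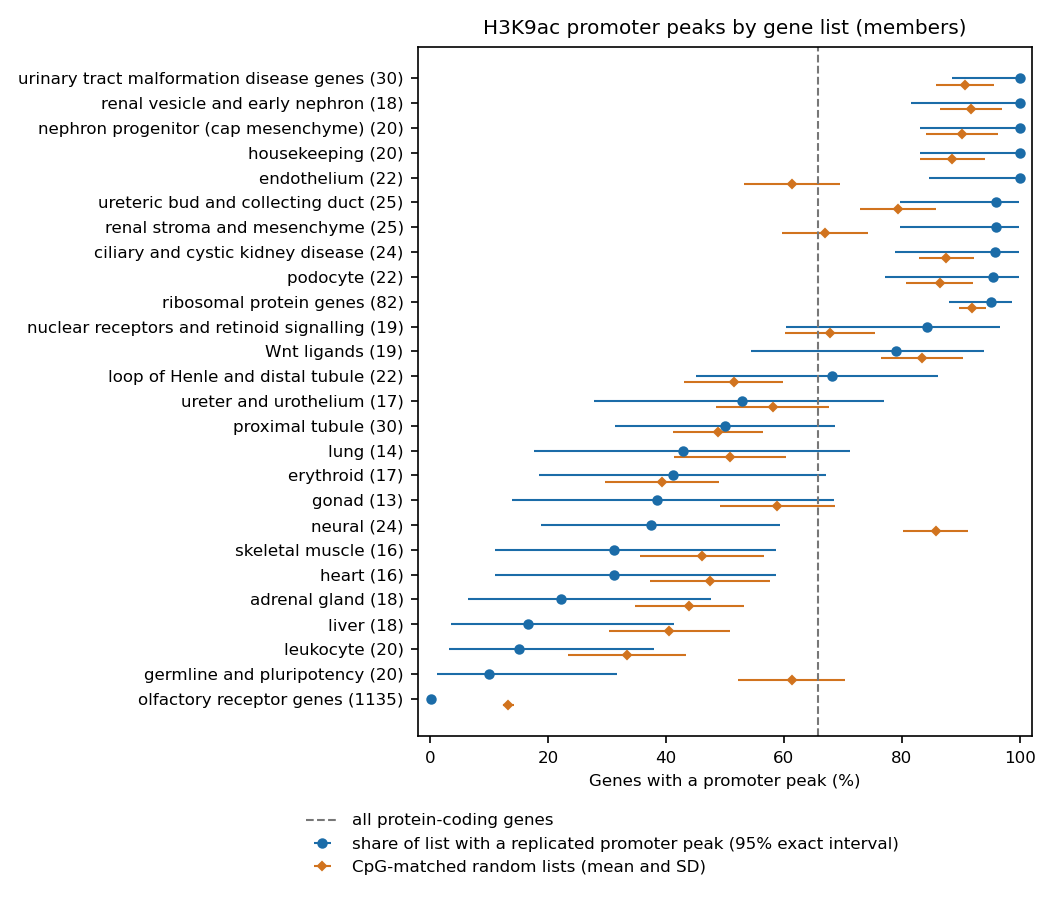
Percent of each fixed list's genes with a replicated H3K9ac promoter peak (blue, with the 95% exact interval), beside CpG-matched random lists (orange, mean and SD), with list sizes in brackets and a dashed line at the 65.7% of all genes. Endothelium at 100% and stroma at 96.0% lie above their matched means of 61.4% and 66.9%, and neural genes at 37.5% lie below their matched mean of 85.7%.

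Genes of mature tubules were marked at lower shares than the lists above, and neither tubule list passed the test against other genes. Of 30 proximal tubule genes, 15 were marked (50%, exact interval 31.3 to 68.7), against 56.7% ± 4.71 (SD, n = 2) in the replicates' own lists. The strongest were the transcription factor gene Maf (17.2), Ggt1 (16.1, a peak shared with the neighbour Lrrc75b), the bicarbonate cotransporter gene Slc4a4 (14.7) and Hnf1a, a regulator of tubule genes (12.6). No peak stood at Cubn, a receptor for protein uptake, the glucose transporter gene Slc5a1, the lactate transporter gene Slc5a12 or the organic anion transporter gene Slc22a6. Of 22 genes of the loop of Henle and distal tubule, 15 were marked (68.2%, exact interval 45.1 to 86.1), and the replicates had 75% ± 9.64 (SD, n = 2). The kinase gene Wnk4 had 20.9, Egf 15.1 at a start site other than its 5′ end, Sim1 10.4 and Ppp1r1a 10.002. The salt transporter genes Slc12a1 and Slc12a3, the uromodulin gene Umod and the potassium channel gene Kcnj1 had no replicated peak, although Slc12a3 had a peak in replicate 1. The adjusted p were 0.103 and 1 by Fisher's exact test, and 1 and 0.164 against CpG-matched lists with means of 48.8% ± 7.60 and 51.5% ± 8.40. The proximal tubule share passed the test as lower at 46.7% with −log10 q of at least 2, at 46.7% with at least 200 bp covered, and at 26.7% with the 20000 strongest peaks alone. The difference between the tubule lists and the other kidney lists was not tested.

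Stromal and endothelial genes stood above random lists matched on CpG content at the gene's 5′ end. Of 25 stromal genes, 24 were marked (96.0%, exact interval 79.6 to 99.9), with the homeobox genes Pbx1 (29.8), Meis1 (27.8) and Meis2 (27.3) and the forkhead gene Foxd1 (16.5), a marker of the cortical stroma, strongest. Pbx1 stood above Meis1 and Meis2 in replicate 1 and below both in replicate 2. The renin gene Ren1 had a peak in replicate 1 but not in the replicated list. All 22 endothelial genes were marked in every list, among them the ETS factor gene Fli1 (20.9), the connexin gene Gja5 (18.3, a peak shared with Gpr89), Ets1 (14.6) and the tight junction gene Cldn5 (10.8). The peaks of Fli1 and Ets1 lay at start sites other than the gene's 5′ end. The matching did not cover such sites, and it was not repeated with marks at 5′ ends only. The matched means were 66.9% ± 7.30 for stroma and 61.4% ± 8.19 for endothelium, with adjusted p of 0.00104 for each, the smallest the random lists allow. By Fisher's exact test the adjusted p were 0.00112 and 0.000532. With the 20000 strongest peaks alone, 77.3% of endothelial genes were marked and the Fisher call ended.

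Markers of other tissues were marked less often than other genes in 8 lists. Of 20 leukocyte genes, 3 had a peak (15.0%), the lymphoid factor gene Ikzf1 (8.03) and, at start sites other than the 5′ end, Coro1a (6.65) and Spi1 (2.89), against 30% without replicate 1 and 25% without replicate 2. Ptprc, Cd68 and Tyrobp had none, and Csf1r, the receptor for a macrophage growth factor, had one in both replicates but not in the replicated list. Of 18 liver genes, 3 had a peak (16.7%), Foxa3 (12.8, shared with Sympk), Cebpa (12.1) and Trf (4.85, shared with Gm20425), and the plasma protein genes Alb, Afp, Apoa1 and Apoa2 had none, though Afp had one in replicate 2 and Apoa2 in replicate 1. Of 18 adrenal genes, 4 had a peak (22.2%), Gata6 (14.0), Ddc (7.29), Hand2 (3.51) and Nr5a1 (3.02), those of Ddc and Nr5a1 away from the 5′ end. The steroid genes Star, Cyp11b1 and Cyp11b2 had none, and Cyp11a1 had one in both replicates alone. Of 20 germline and pluripotency genes, 2 had a peak (10%), Dazl (9.47) and Tdrd1 (3.44), and Pou5f1, Nanog, Ddx4 and Sycp3 had none. Among 1135 olfactory receptor genes, 1 had a peak, Olfr1033 (0.0881%, exact interval 0.00223 to 0.490), and Olfr1, Olfr10, Olfr1000 and Olfr1002 had none. The olfactory receptor share was 0.264% without replicate 1 and 0.441% without replicate 2.

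In skeletal muscle and heart, 5 of 16 genes each had a peak (31.2%). In muscle, the peaks of Mylpf (21.1), Actn3 (20.8) and Ckm (7.24) were shared with the neighbours Tbc1d10b, Zdhhc24 and Klc3, Des had 7.03, and the myogenic factor genes Myod1, Myog, Myf5 and Myf6 had none. In heart, the peak of Myl3 (15.1) was shared with Pth1r, Ryr2 had 7.16, Tnni3 4.65 and Myh7 3.03, and Nkx2-5, Myh6, Tnnt2 and Tbx5 had none, though Tbx5 had one in replicate 2. The Tnni3 peak lay away from the 5′ end, and Myh7 had a peak in replicate 1 but not in replicate 2. Of 24 neural genes, 9 had a peak (37.5%), led by Phox2a (14.3), Ascl1 (4.90), Lhx2 (4.65) and Isl1 (4.15), and Neurod1, Neurog2, Olig2 and Tlx3 had none, though Neurog2 had one in replicate 1 and Olig2 in replicate 2. The Phox2a peak lay at a start site other than the 5′ end.

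By Fisher's exact test, the adjusted p were 2.86e-05 for leukocyte, 0.000117 for liver, 0.000662 for adrenal gland, 3.20e-06 for germline, 0.00976 for muscle and for heart and 0.0117 for neural genes. Against CpG-matched lists, 3 of the 8 lists were lower, with adjusted p of 0.00104 for each: olfactory receptor (matched mean 13.3% ± 0.9499), germline (61.3% ± 8.99) and neural genes (85.7% ± 5.49). The matched adjusted p were 0.191 for leukocyte, 0.0995 for liver, 0.105 for adrenal gland, 0.314 for muscle and 0.29955 for heart. By Fisher's exact test, the neural call held with a peak required in both replicates' own lists (41.7%, adjusted p = 0.0252) but not in a single replicate: 62.5% of neural genes were marked without replicate 1 (adjusted p = 0.753) and 50% without replicate 2 (adjusted p = 0.100), and over all alternatives the adjusted p ran from 1.84e-06 to 0.830. In the pooled list, 16 of 24 neural genes were marked (66.7%), beside 68.1% of all genes. The CpG-matched test was run on the replicated list alone, so the matched neural call was not tried on the other lists. The muscle call ended with promoters of 2500 bp on each side.

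A further 4 lists of other cell types passed neither test. Erythroid genes were marked in 7 of 17 (41.2%), with none at Gata1, Alas2, Slc4a1 or Epb42; gonad genes in 5 of 13 (38.5%), with no replicated peak at Amh, Gata4, Dmrt1 or Cyp17a1, of which Gata4 and Dmrt1 had one in replicate 2. Lung genes were marked in 6 of 14 (42.9%), with none at the surfactant genes Sftpc, Sftpb, Sftpa1 and Sftpd. Ureter and urothelium genes were marked in 9 of 17 (52.9%), with no replicated peak at the uroplakin genes Upk1a, Upk1b, Upk2 and Upk3a, of which Upk1a had one in both replicates and Upk2 in replicate 2. By Fisher's exact test the adjusted p were 0.0562, 0.0963, 0.107 and 0.334 in this order. Without replicate 2, the erythroid list (41.2%) and the gonad list (38.5%) passed the test as lower. The erythroid list also did so with the pooled list (41.2%), and both did with the 20000 strongest peaks alone (29.4% and 23.1%).

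Genes expressed in most cells and genes of kidney disease were marked almost throughout. All 20 housekeeping genes were marked, with the actin gene Actb (46.4), Ywhaz (43.5), Ppia (36.2) and the elongation factor gene Eef2 (31.8) strongest, and 78 of 82 ribosomal protein genes were marked (95.1%). The Ywhaz peak lay away from the 5′ end. Rpl10l, Rpl39l, Rpl3l and Rps27rt had no replicated peak, though Rpl3l had one in both replicates. All 30 urinary tract malformation genes were marked, 16 of which are also in other lists, with Nrip1 (32.9), Sall1, Foxc1 and Pbx1 strongest. Of 24 genes of ciliary and cystic kidney disease, 23 were marked (95.8%), with the polycystin gene Pkd2 (26.0) and the ciliary genes Ift140 (23.8, shared with Cramp1l) and Invs (23.4, shared with Erp44) among the strongest. The peak of highest signal counted for Nek8 (34.2) was shared with Traf4 and lay away from the 5′ end of Nek8. In the replicates' own lists, the promoter signal of Nek8 was 15.0 and 11.7. By Fisher's exact test the adjusted p were 0.00112, 2.97e-09, 3.06e-05 and 0.00157, and against CpG-matched lists 0.153, 0.314, 0.164 and 0.267, so that no call held against CpG content. The housekeeping and urinary tract malformation lists were marked in full, so the matched test could not have called them higher. Retinoid signalling genes were marked in 16 of 19 (84.2%; Rbp1, Aldh1a1 and Cyp26c1 had none) and Wnt ligand genes in 15 of 19 (78.9%; Wnt1, Wnt3, Wnt3a and Wnt8a had none), with adjusted p of 0.109 and 0.347 by Fisher's exact test. Over the 26 lists, 10 were higher, 8 lower and 8 did not pass, and against CpG-matched lists 2 were higher and 3 lower.

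The third comparison asked how strong and how wide the mark was at the marked members of each list. The random lists for signal and width were not matched on CpG content, number of start sites or gene span. Ranks were therefore not separated from these traits. In permutation tests of list membership, the strongest promoters belonged to ribosomal protein genes (median rank 89.6%, adjusted p = 0.00240) and housekeeping genes (82.0%, 0.00343). Tubule genes that were marked had weak peaks: the median rank was 10.1% for the proximal tubule and 12.3% for the loop of Henle and distal tubule (adjusted p = 0.00288 each by permutation). Endothelial (15.3%, 0.00240), Wnt ligand (14.0%, 0.00343), stromal (24.4%, 0.0102), urothelial (15.5%, 0.0314) and ureteric bud genes (26.7%, 0.0314) also ranked low. So did neural (5.66%), heart (8.07%) and adrenal genes (10.5%), with adjusted p of 0.00288, 0.0149 and 0.0324 in resampling tests on 9, 5 and 4 genes. Of 24 lists tested, 2 were higher, 10 lower and 12 did not pass; germline and olfactory receptor genes, with under 3 marked members, were left out. The urothelial, adrenal, stromal and ureteric bud calls ended when strength was the sum of signal by width, and the ureteric bud rank was 30.8% without replicate 2 and did not pass. The adrenal rank was 6.41% without replicate 1, and the call held. The rank of the gonad list was 6.61% and of the retinoid list 22.1% without replicate 1, and that of the leukocyte list 6.74% and 3.105% without replicate 1 or 2, which passed as lower. Lists tested only in a single replicate also passed as lower: olfactory receptor genes in both (4.80% and 2.11%) and germline genes without replicate 2 (2.70%). In all, 14 of 25 lists were lower without replicate 1 and 12 of 26 without replicate 2.

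Width gave another order. Podocyte (median domain 4242 bp, rank 91.8%), renal vesicle (4031 bp, 90.3%) and nephron progenitor genes (3945.5 bp, 89.9%) had wide domains, beside 4125 bp (91.1%) for housekeeping genes, while the signal ranks of these 3 kidney lists, 48.0%, 27.8% and 33.4%, did not pass the test. With strength as the sum of signal by width, a measure that itself holds width, podocyte genes turned to a high rank. Urinary tract malformation genes had 3742.5 bp and ribosomal protein genes 2946 bp. Each of these 6 lists had an adjusted p of 0.000686, the smallest the random lists allow. Retinoid (3816.5 bp, adjusted p = 0.00120), endothelial (2818 bp, 0.0176) and ureteric bud genes (2749.5 bp, 0.0176) were also wider than other marked genes in permutation tests, with 1954 bp the median of all. Loop of Henle genes were narrower (1154 bp, adjusted p = 0.0165), and so were heart (692 bp, 0.0168) and neural genes (387 bp, 0.000686) in permutation tests on 5 and 9 genes. Over 24 lists, 9 were wider and 3 narrower. With no joining of peaks, the retinoid, endothelial, ureteric bud, loop of Henle and heart calls ended. With gaps of up to 3000 bp joined, the endothelial and ureteric bud calls ended and stromal (rank 79.0%) and Wnt ligand genes (76.5%) passed as wider. The neural rank for width, 2.82%, was 11.5% without replicate 2, and the call held. The number of narrower lists was 5 of 25 without replicate 1 and 6 of 26 without replicate 2. Leukocyte genes were added in both (ranks 4.50% and 2.54%). The other additions had too few marked members in the replicated list to be tested, namely olfactory receptor genes in both and germline genes without replicate 2. Stromal genes were wider without replicate 1 (rank 75.9%).

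**Figure D2:**
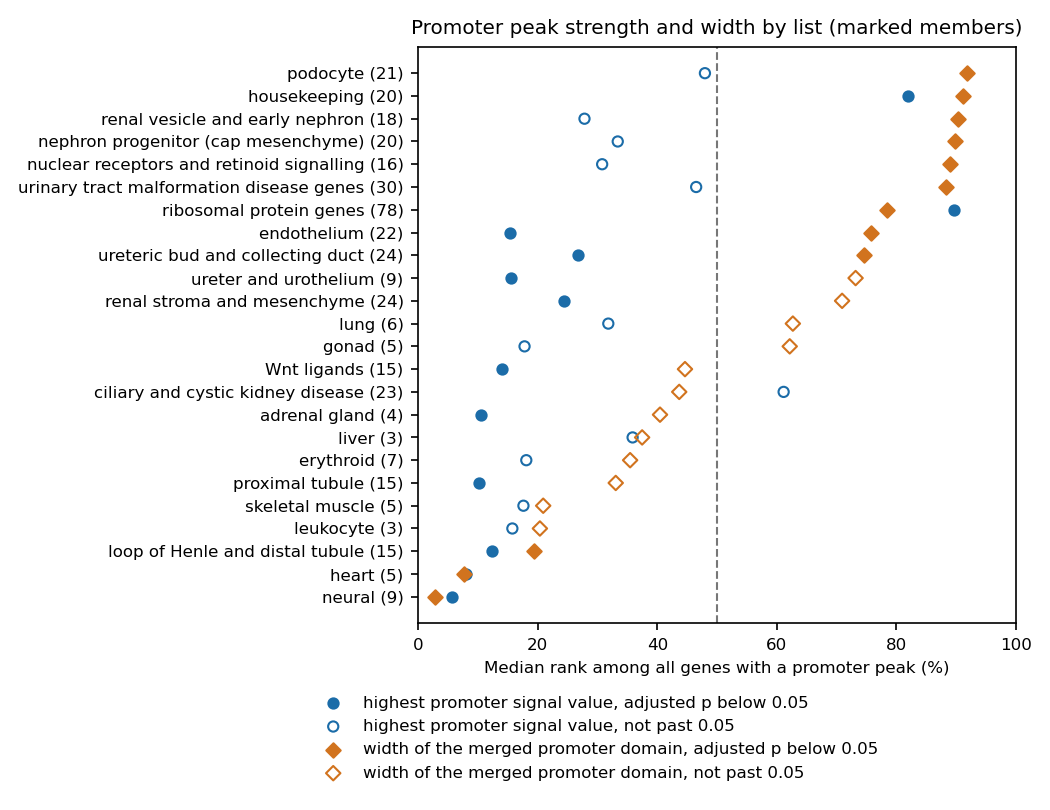
Median rank of promoter signal (blue circles) and of merged domain width (orange diamonds) among all marked genes, in percent, for the marked members of each list (numbers in brackets). Filled symbols passed an adjusted p of 0.05 against random lists, and the dashed line is at 50%. Podocyte genes rank at 48.0% for signal and 91.8% for width.

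The widest domains of all lay in the Hox clusters, homeobox genes ordered along the chromosome by the body level at which they act. A single domain of 79346 bp on chromosome 11 (96276092 to 96355437) touched the promoters of Hoxb2, Hoxb3, Hoxb4, Hoxb5, Hoxb6, Hoxb7 and Hoxb8. A domain of 49959 bp on chromosome 6 (52199949 to 52249907) touched Hoxa10, Hoxa11 and the annotated gene Gm28308, and, beyond the genes the rule named, Hoxa3, Hoxa5, Hoxa6, Hoxa7 and Hoxa9 at the same width. Promoter peaks stood at 35 of 39 Hox genes, and at 36 in each replicate. All 12 genes of paralog groups 1 to 4, all 11 of groups 5 to 8 and all 10 of groups 9 to 11 were marked, in the replicated list and in each replicate. Of 6 genes of groups 12 and 13, 2 were marked, Hoxd12 (signal 6.03) and Hoxd13 (6.04). Hoxa13 had a peak in each replicate and the pooled list but not in the replicated list, and Hoxb13, Hoxc12 and Hoxc13 had none in any list. Replicated peaks covered 70.0% of the Hoxa, 54.6% of the Hoxb, 47.3% of the Hoxc and 64.0% of the Hoxd cluster. The replicates' own values were 67.5% and 67.9%, 54.1% and 53.3%, 48.0% and 45.3%, and 63.9% and 60.5%. No test was made across clusters.

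**Figure D3:**
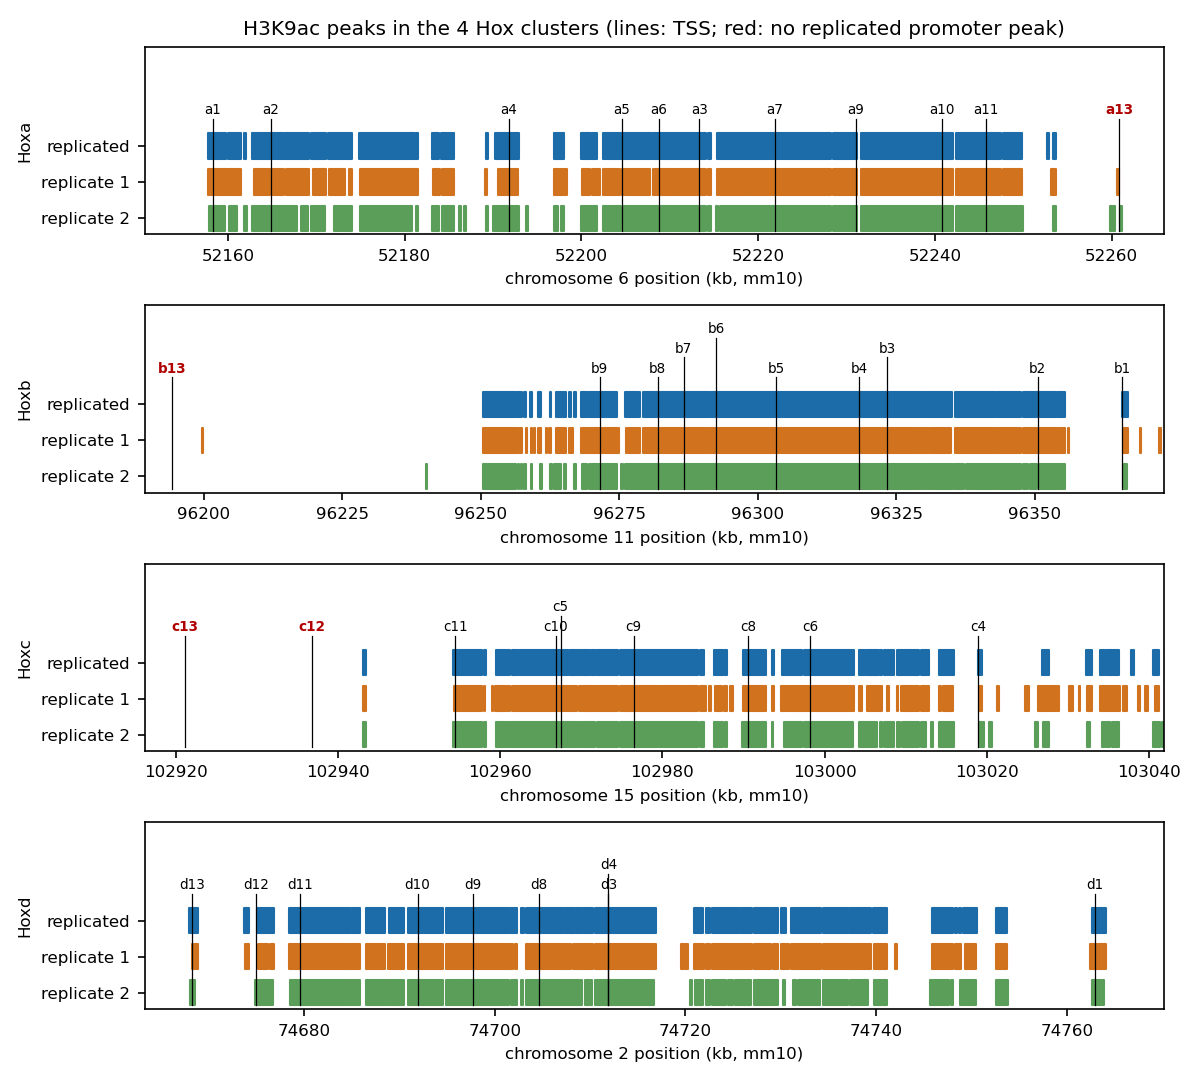
H3K9ac peaks over the 4 Hox clusters by position in kb (mm10), for the replicated list (blue), replicate 1 (orange) and replicate 2 (green), with a line at each gene's annotated 5′ end. The names in red, a13, b13, c12 and c13, are the 4 of 39 genes without a replicated promoter peak.

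The fourth comparison asked whether marked sites away from promoters gathered near genes of the kidney. Of the replicated peaks, 20598 (46.4%) were distal, and a gene had 1.97 ± 3.12 of them within 50000 bp (mean and SD over genes). Nephron progenitor genes had 5.1 per gene against 2.74 in matched lists, podocyte genes 5.09 against 2.55, ureteric bud genes 4.76 against 2.52 and retinoid signalling genes 4.74 against 2.27. Endothelial genes had 4.73 against 2.66, stromal genes 4.32 against 2.55 and skeletal muscle genes 3.44 against 1.43. None of these passed: the adjusted p were 0.0555, 0.0555, 0.0537, 0.0537, 0.0832, 0.0988 and 0.0555 in this order. The power of the adjusted test on these lists is unknown, so its outcome does not show that an excess was absent. Proximal tubule genes had 1.83 against 1.64 (permutation test, adjusted p = 0.801). Olfactory receptor genes alone were lower, with 0.0969 against 0.691 (permutation test, adjusted p = 0.00520). At an unadjusted p under 0.05 there were 8 lists higher and 1 lower, against 0 and 1 after adjustment; the 8 are the 7 above and the germline list, with 1.9 against 0.878. With a reach of 20000 bp, 8 lists were higher after adjustment, the 7 above and the renal vesicle list. In each replicate's own list, the means of all lists and of their matched lists were higher than in the replicated list. Without replicate 1, the retinoid list passed as higher, with 9 per gene against 4.44 in matched lists. The olfactory receptor mean was 0.142 against 1.24 without replicate 1 and 0.199 against 1.40 without replicate 2, lower in both.

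The strongest distal peaks lay mostly outside coding genes. The first was on chromosome 12 (8640745 to 8641714, signal 31.8), 33187 bp from the TSS of Pum2, which encodes an RNA-binding protein. The next were on chromosome 15 (85668823 to 85673334, 31.7) in the noncoding gene Lncppara, and on chromosome 4 (143160851 to 143162200, 29.6) in an intron of Prdm2. Another on chromosome 4 (8910513 to 8912542, 27.5) lay 56368 bp from Chd7, a chromatin remodeller gene. The other 6 had signal values of 25.5 to 27.4, and their nearest TSSs were those of Spag6, Chd2, Nufip1, Pcbp1, Zfp52 and Ptma.

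The fifth comparison asked which consensus words were frequent in distal peaks. The word of CTCF, an insulator protein, was in 2.18% of 20596 distal windows and 0.397% of 27720 flanks (odds ratio 5.58, Fisher's exact test, adjusted p = 6.01e-74), against an odds ratio of 0.673 for the reversed word. The words of NFI (2.99, 0.00701), of GRHL epithelial factors (2.95, 3.87e-05), ETS factors (2.17, 9.76e-13), NRF1 (2.12, 0.0115), WT1 (1.67, 1.59e-80), Six2-type progenitor factors (1.66, 1.40e-05) and TEAD factors (1.18, 2.51e-14) were also more frequent, each above its reversed word. The muscle E-box was in 34.5% of windows and 21.9% of flanks (odds ratio 1.87, Fisher's exact test, adjusted p = 8.73e-204; reversed 1.36). The PAX2/8 word had 1.83 (Fisher's exact test, adjusted p = 5.81e-13) and lay below its reversed word at 2.17. The GATA (0.793), POU (0.811) and TCF/LEF words (0.861) were less frequent, with reversed words at 0.622, 0.902 and 0.828. The HNF1, HNF4, AP-1, HOX and RFX words did not pass, with odds ratios of 1.04, 1.21, 0.999, 0.921 and 1.25. By Fisher's exact test, 10 of 18 words were higher, 9 of these above their reversed word, 3 lower and 5 not past. Reversal does not keep CG pairs: the ETS and GRHL words hold CG and their reversed words do not. For them, the word cannot be told apart from CpG content. The reversed HOX word holds CG and had an odds ratio of 1.85. The reversed E-box word also holds CG, unlike the E-box, and was in 0.830% of flanks, so it was no like control. Reversed NFI and CTCF words likewise hold a fixed CG pair that the words lack. The reversed NFI and NRF1 words were each in 0.0049% of windows and 0.0036% of flanks. The reversed CTCF word was in 0.0097% of windows and 0.0144% of flanks. For NFI, NRF1 and CTCF, the reversed word was thus too rare to serve as a control. In the central 200 bp the odds ratios of CTCF and NRF1 turned to 0.872 and 0.908 and did not pass, and the NFI call ended. Another word, which did not pass in the 500 bp windows, gained a call there. The CTCF odds ratio was 3.53 without replicate 1 and 3.36 without replicate 2, and the call held. Without replicate 2, the NFI word did not pass (1.57) and the HNF4 word did (1.19).

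The last comparison was between the replicates. The strongest peaks were shared nearly throughout, and the weak ones were mostly found in 1 replicate. Of replicate 1's peaks, 55.5% (44344 of 79905, exact interval 55.2 to 55.8) overlapped a peak of replicate 2, and 61.0% (43539 of 71327, 60.7 to 61.4) did so the other way. Random placement gave 2.87% ± 0.0592 and 3.17% ± 0.0760 (SD over 100 placements). By signal decile, the share rose from 27.4% in the lowest to 100% in the highest in replicate 1, and from 30.8% to 100% in replicate 2. Among shared peaks 51.7% and 52.2% lay at promoters, against 13.4% and 13.8% of unshared peaks in replicates 1 and 2. Across 14397 genes marked in both, promoter signal had a Spearman correlation of 0.924 and a Pearson correlation of 0.934 on the log2 scale; genes are not independent replicates. The median gene differed by 5.87 rank points. The strongest unshared peaks of replicate 1 were on chromosome 10 (78487535 to 78487880, signal 7.71), 22775 bp from Pdxk, and, at the same signal value, on chromosome 7 (41598907 to 41599198), 186 bp from the TSS of 2610021A01Rik, and that of replicate 2 on chromosome 5 (137377306 to 137377622, 7.42), in an intron of Ephb4. The others lay nearest to or in Mllt1, Mast4 and Zfp429 in replicate 1, and Phf7, Crem, Gtf2h3 and Ndufs1 in replicate 2. All 10 were in the pooled list. With a 50% reciprocal overlap the shares were 38.4% and 43.0%, and with the 20000 strongest peaks of each list 89.2% and 89.7%.

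**Figure D4:**
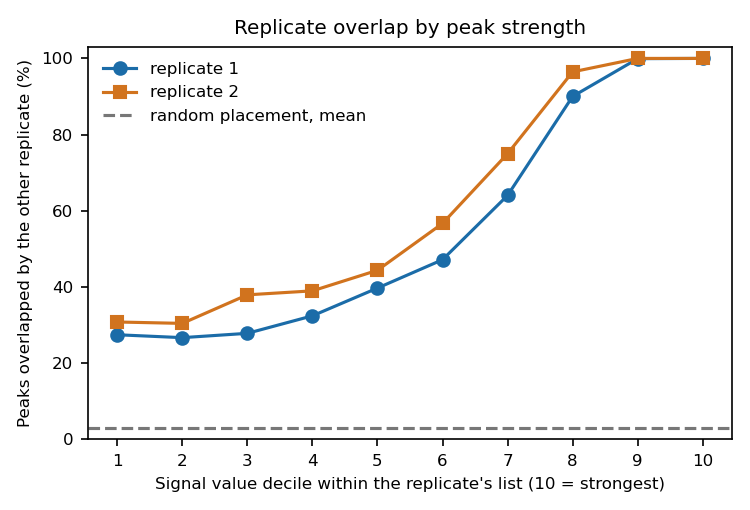
Percent of each replicate's peaks overlapped by a peak of the other (y axis) by decile of signal value within its own list (x axis, 10 strongest), for replicate 1 (blue) and replicate 2 (orange), with the mean of random placements as a dashed line. The share is 27.4% and 30.8% in the lowest decile and 100% in the highest.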

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

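The tests of signal strength, of promoter CpG content, of unmarked tubule genes in other lists and of abundant-transcript genes were chosen only after the results were seen; those of region edges, GC content and shared promoters were set before. The design has 1 group, so no biological explanation was tested for any pattern.

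Many peaks were called in 1 replicate only, 35561 in replicate 1 and 27788 in replicate 2. Of the peaks in the 2 top signal deciles, 0.0313% lacked an overlap in replicate 1 and 0 in replicate 2, against 72.6% and 69.2% of the lowest decile; this restates the overlap by strength, so weak signal near the calling threshold was not tested apart from it and stays open. Edges of regions marked in both also stay open, with 47.7% and 51.8% of unshared peaks within 2000 bp of a peak of the other replicate, against 9.29% and 9.65% by chance placement. These shares fall around the bound of 50%, so edges cannot be told apart from separate sites. A GC difference between the libraries also cannot be told apart, since the medians of unshared peaks differed by 1.21 percentage points (51.5% and 50.3%), between the bounds of 1 and 2 points.

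Of 52 tubule genes, 22 had no replicated promoter peak. Promoter CpG content is a candidate explanation, since the marked share of 57.7% lay within 2 SD of CpG-matched random lists (49.9% ± 5.64, permutation p = 0.230). Weak signal near the calling threshold cannot be told apart from lack of the mark: 7 of the 22 (31.8%) had a promoter peak in at least 1 of the other 3 lists, between the bounds of 25% and 75%, and depth is unknown.

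Promoter peaks stood at 37 genes of the adrenal gland, gonad, neural, muscle, heart, liver, lung and germline lists that are in no kidney list, which leaves out Rspo1 and Etv5. The tables argue against a promoter shared with a neighbouring coding gene as the source of most of them: 8 of 37 peaks (21.6%, exact interval 9.83 to 38.2) overlapped another coding promoter, against 7 of 159 genes (4.40%) in kidney lists. The interval lies below the 50% that this source needed but passes the 25% set before as the bound against it. The use of the interval was decided after the value was seen. The 8 shared peaks stay open, and they include those of highest signal rank among the 37. These were at Mylpf (75.7%), Actn3 (74.5%), Inha (57.8%) and Myl3 (49.4%). The next in rank, at Phox2a (45.8%) and Gata6 (44.1%), were not shared. Cells of these tissues in the samples cannot be told apart, since 13 of 52 genes of their most abundant transcripts were marked (25%, exact interval 14.0 to 38.9), 4 of 9 for heart, 3 of 7 for muscle, 5 of 7 for nerve, 1 of 7 for germline and 0 of 8, 5 and 9 for liver, lung and adrenal gland, and 5 of the 39 others had a peak in another list, among them Cyp11a1, Afp and Apoa2. Weak signal near the calling threshold may account for part, as the 29 peaks that overlap no other coding promoter had a median signal rank of 7.93%, against 24.7% for kidney lists.

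Outside the protein-coding genes, long noncoding genes were taken by their annotation label, with the label processed transcript included. Of 7074 such genes whose every TSS lay over 5000 bp from a coding TSS, 860 had a replicated promoter peak (12.2%, exact interval 11.4 to 12.9). This was set against a count of 0 alone and not against a chance or CpG-matched share. The replicates had 15.7% ± 0.520 (SD, n = 2). Sequences other than chromosomes 1 to 19, X and Y, which no comparison used, held 5 replicated peaks.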

How the results depend on the processing

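The alternatives without peaks shared with a neighbour and with both replicates' own lists were chosen after seeing the data; all others were planned. No call of a list's promoter share turned direction under any alternative run, and over all lists and alternatives 282 values kept their call or lack of one, 22 lost the call (13 with the CpG-matched background, which left 2 lists higher and 3 lower) and 8 gained one. Without peaks shared with a neighbour, the housekeeping (75%) and ciliary (70.8%) calls ended, and so did the neural and heart calls, although their shares stayed at 37.5% and 31.2%. Peaks shared by the replicates were 38.4% and 43.0% with 50% reciprocal overlap, 61.8% and 65.3% with −log10 q of at least 2, 58.9% and 58.6% with equal numbers of top peaks, 89.2% and 89.7% with the top 20000, and 55.1% for replicate 1 on chromosomes 1 to 19. Peaks at promoters were 44.1% with 500 bp windows, 58.6% with 2500 bp, 78.75% with the top 20000, 46.6% with 200 bp covered, 34.8% in the pooled list and 34.7% to 37.2% without a replicate; bases at promoters were 41.0%, 73.2%, 73.4% (top 20000), 52.0% (pooled) and 53.4% to 54.8%. Marked genes were 65.0% and 66.9% with these windows, 59.7% with the top 20000, 68.1% pooled, 62.2% at 5′ ends only and 67.1% to 67.7% without a replicate. By sum of signal by width, 4 lists were stronger and 6 weaker, and podocyte and urinary tract malformation genes turned to ranks of 87.2% and 70.5%. Narrower lists were 1 with no joining and 5 to 6 without a replicate (1 and 2 of them lists not tested otherwise), and with 3000 bp gaps Wnt ligands turned to a rank of 76.5%. Lists with more distal peaks were 8 at 20000 bp, 1 at 100000 bp, 2 beyond 2500 bp from a TSS, 4 with the top 20000 and 0 to 1 without a replicate. Marking in the lowest and highest CpG decile was 7.57% and 98.9% pooled, and 7.2015% to 7.29% and 98.7% to 98.8% without a replicate. In the central 200 bp, CTCF and NRF1 turned to 0.872 and 0.908. The wider and narrower windows move the promoter values by construction; for the other changes the cause was not tested. No paired analysis was possible because there is 1 group. Unknown depth limits every statement on missing peaks.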

Other observations

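All values in this part were chosen after the results were seen, and no test was made of them. The widest domain at each Hox gene was left out, and contact of other domains with further Hox start sites was not checked. Of the rest, the widest 10 were, in order, at Nr2f2, a nuclear receptor gene (26129 bp, chromosome 7, 70345738 to 70371866), Cxxc5 (23106 bp), Gata3, a factor of the nephric duct and ureteric bud (22160 bp, chromosome 2, 9867991 to 9890150, shared with 2 neighbours), and Bahcc1 (20900 bp). They were followed by Meis2 (20584 bp), Gm28230 (20218 bp, within the Hoxd cluster), Pax2 (18427 bp), Cirbp (17639 bp, shared with a neighbour) and the T-box genes Tbx2 (16649 bp) and Tbx3 (16563 bp). Of these, Gata3, Meis2, Pax2 and Tbx2 are in fixed lists.

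The genes with the most distal peaks within 50000 bp were Gse1 (42), Ahdc1 (35) and the Hedgehog pathway gene Sufu (35), followed by Casz1 (32), Msi2 (32), the receptor gene Notch1 (31) and Rere (31). Actn4, a podocyte gene, had 24. Long genes and genes with many start sites can collect more peaks, and this list was not matched for either.

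The genes labelled long noncoding with the highest promoter signal included 1810026B05Rik (47.7, chromosome 7, 73556663 to 73558498) and Mir17hg, the host gene of a microRNA cluster (36.4, chromosome 14, 115039998 to 115043049). Next were Ptpmt1 (34.3), annotated as a processed transcript, and the snoRNA host gene Snhg6 (33.4). Distal peaks of the lowest signal decile had a median CpG observed/expected of 0.238 and those of the highest decile 0.453, against 0.706 at marked promoters. On chromosome X, 442 of 948 coding genes (46.6%) were marked, and on chromosome Y 4 of 183 (2.19%). Chromosome 12 had the highest share, 78.1% of 643 genes.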
